A study of Mus musculus with 20 samples.

How the data were processed

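Gene expression was measured on 20 arrays with 2 channels each of mouse macrophages, 5 for each of the 4 genotypes wild-type, TRIF-KO, MyD88-KO and double-KO, at 1, 2, 4, 8 and 16 h of LPS. Per the labels' protocols, bone marrow cells of age and gender matched C57BL/6 mice were differentiated for 6 days in medium with M-CSF, replated, and kept in serum-free medium with 200 ng/mL LPS from Salmonella or without it, and total RNA was isolated with TRIzol and labelled with a kit for 2 colours. Groups, time points and dyes were taken from the labels, which put LPS-treated RNA in Cy5 on 19 arrays and in Cy3 on 1, the MyD88-KO array of 2 h. Its ratio was turned round before use. The arrays lay on 5 slides of 4, and the scans fell on 2 days, per the file headers: wild-type 1 to 8 h on the first slide, wild-type 16 h with TRIF-KO 1 to 4 h on the second, TRIF-KO 8 and 16 h with MyD88-KO 1 and 2 h on the third, MyD88-KO 4 to 16 h with double-KO 1 h on the fourth, and the other double-KO arrays on the fifth. The first 3 slides were scanned on day 1 and the others on day 2.

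Per the file headers, the deposited scanner files were made with Agilent Feature Extraction 10.10.1.1, and they give for each spot the mean intensity and the median background intensity of both channels before correction. They also hold processed intensities, which the authors' scanner software had corrected for background and dye, and the log10 ratio of processed Cy5 over Cy3, per the file headers. The deposited value table of the whole series equalled that log10 ratio on every array within 5e-10, each column had a median of 0 over non-control spots, and no further centring or turning of the swapped array had been applied, so its scale, centring and direction were settled. Coordinates are those of mm9 in the file headers. No genome was used here, so the position of a probe within exons was not annotated.

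Background was corrected with normexp (offset 50) on the mean and background intensities in limma 3.58.1 under R 4.3.3, with data.table (version 1.17.8) for reading. Control spots were left out after that step, outlier spots of the scanner software were set to missing, saturated spots were kept (at most 81 per array and channel), and each array was normalized by loess. Untreated levels came from the Cy3 channel of the 19 arrays with untreated RNA in it, after loess and quantile normalization of the mean log intensity between arrays. The levels of the targeted and sex-linked genes by label also hold the Cy5 value of the swapped array, which the fits of untreated levels leave out. Spots of 1 probe were averaged. A probe was kept if it was well above background in at least 1 channel on at least 3 arrays, which left 28304 of 39429 probes. Each gene was represented by its kept probe with the highest mean intensity, giving 21963 genes, of which 5039 had more than 1 kept probe and 235 a missing ratio on at least 1 array. Names were matched to the RefSeq table by accession for 27234 probes, by symbol for 3576 and by synonym for 563, and 8056 kept the name in the file. Among called genes with other kept probes, at least 1 probe had the opposite sign for 107 of 707 in wild-type against double-KO, 36 of 424 in TRIF-KO against double-KO, 67 of 616 in MyD88-KO against double-KO and 355 of 1641 in untreated double-KO against wild-type. A level that was well above background on no array of a group was used only as a bound, "at least N-fold", against the mean of the higher of the probe's own value and the lowest value well above background on each array. Such bounds are open to dye bias, since dyes were not balanced.

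Log2 ratios of LPS over untreated were fitted for all 20 arrays together with limma's moderated test, with time point as a block, and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. The fit gave the mean response per genotype, the 6 differences between genotypes, and the departure from additivity of both adapters on the log2 scale. Slopes over log2 time were fitted per genotype, and untreated levels were fitted with genotype and time point or with genotype and slope. The spread is that between the 5 time points of a genotype after the shared time effect. Same-numbered arrays are arrays of the same time point, per the labels. Deviations from the group means correlated at 0.74 to 0.83 for pairs of wild-type and TRIF-KO ratios, 0.28 to 0.70 for wild-type and MyD88-KO and 0.22 to 0.57 for TRIF-KO and MyD88-KO, so these numbers pair the ratios, and all pairs of untreated levels were above 0.1 as well. Pairs with double-KO ratios reached down to -0.20 and were not paired by this check. The main fit still blocked time point for all 20 arrays. Differences from double-KO ratios therefore rest on a shared time effect that this check does not bear out. Their counts without the block are given with each result.

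Before the data were examined, 28 gene lists were fixed: 9 lists of markers of T cells, B cells, neutrophils and granulocyte precursors, fibroblasts and stroma, dendritic cells, NK cells, erythroid cells, mast cells and basophils, and osteoclasts, and lists of immediate early and NF-kB feedback genes, inflammatory cytokines, chemokines, interferon-stimulated genes, acute phase and matrix proteins, negative regulators of Toll-like receptor signalling, enzymes of nitric oxide, itaconate and prostaglandins, glycolysis, cholesterol biosynthesis, cell cycle, MHC class I, MHC class II, costimulation, macrophage identity, lysosome, oxidative phosphorylation, stress, housekeeping and components of the Tlr4 pathway. Each was tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, for 9 results, and after the data were seen also for both differences of slopes. The groups, the main models, the alternatives and the rule for named genes were also set before the data were examined. By that rule the text takes, for each difference between genotypes, the 10 largest positive and 6 largest negative values past the threshold with the same sign at all 5 time points, up to 4 members per list, 6 per direction for the other results, and 28 inflammatory and interferon genes whatever their values. Not all of these are printed. The levels of Ankrd29, Eif2s3y and Xist in every group were added after their values were seen.

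Alternatives were no background correction, the scanner's processed intensities, the deposited value table, scaling of log ratios between arrays, quantile normalization of Cy3 alone, no or a stricter filter on dim probes, the mean of all probes of a gene, a dye term, slide as a fixed or random block, trend and robust options of limma, no block of time points, only the groups compared, the swapped array added to the untreated fit, and each array and each time point left out. After seeing the data, scan day as a block and fits without the MyD88-KO arrays of 1 and 2 h, without 8 and 16 h, without double-KO arrays and without TRIF-KO arrays were added. The fits were tested on simulated data. These were independent normal noise with each gene's residual SD, around the gene's mean for untreated levels, with known changes added. The noise was equal in all genotypes and not correlated within slides, so the shares that follow need not hold for the real arrays. For wild-type minus TRIF-KO, 28.4%, 82.1% and 95.5% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered, with 2.84% false calls, over 21728 genes. For TRIF-KO minus double-KO the shares were 32.8%, 73.1% and 95.5% with 10.7% false calls, for the departure from additivity 17.9%, 64.2% and 77.3% with 6.14%, and for untreated double-KO minus wild-type, over 21729 genes, 50.7%, 85.1% and 97.0% with 3.73%. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15. Supernatants, which the labels mention, were not analysed here.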

Results

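Messenger RNA was measured on 20 arrays with 2 colours each in macrophages grown from the bone marrow of C57BL/6 mice with M-CSF-conditioned medium of L929 cells. By their labels the cells were wild-type, MyD88-KO, TRIF-KO, or without both MyD88 and TRIF (double-KO). MyD88 and TRIF (gene Ticam1) are the adapters through which the receptor Tlr4 signals when it meets LPS, a component of the bacterial outer membrane. LPS was given at 200 ng/mL for 1, 2, 4, 8 or 16 h, and each array set LPS-treated cells against untreated cells of the same genotype and time. The genotypes ask which part of the LPS response runs through each adapter. Each genotype had 5 arrays, 1 per time point, so its spread holds the variation between time points as well as noise. Nothing in the labels tells whether the arrays came from separate animals or cultures, and p-values therefore measure only the spread between these samples. Of the 43020 non-control spots per array, between 52.8% and 69.6% were well above background in a channel, and 21963 genes were represented. The number of arrays limits the precision of every value.

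The targeted genes were examined first, in the untreated cells. The Ticam1 probe (mm9, chromosome 17, 56409265 to 56409324) read 10.6 ± 0.19 (SD, n = 5) in wild-type, 10.5 ± 0.19 in MyD88-KO and 7.28 ± 0.04 in double-KO cells, in normalized log2 intensity. Of the 5 MyD88-KO values 1, that of 2 h, came from Cy5 and the others from Cy3. In the arrays labelled TRIF-KO it read 10.8 ± 0.28, at the wild-type level on every array, so the transcript does not bear out that label. It does not refute the label either, since an allele that leaves the transcript in place stays open. The Myd88 probe (mm9, chromosome 9, 119245322 to 119245381) read 14.4 ± 0.41, 14.5 ± 0.48, 14.2 ± 0.17 and 14.0 ± 0.13 in wild-type, TRIF-KO-labelled, MyD88-KO and double-KO cells. It was bright in every group, so it bears out no loss of MyD88 and the MyD88-KO and double-KO labels are taken as given. Tlr4 (mm9, chromosome 4, 66503470 to 66503529) read 13.5 ± 0.31 in wild-type, 13.6 ± 0.34 in TRIF-KO-labelled, 13.5 ± 0.41 in MyD88-KO and 13.5 ± 0.06 in double-KO cells. Other genes set the arrays apart by label. Ankrd29 read 13.3 ± 0.26 in wild-type and 7.23 ± 0.25, 7.44 ± 0.19 and 7.75 ± 0.17 in the TRIF-KO-labelled, MyD88-KO and double-KO cells. The Y-linked Eif2s3y read 14.2 in the TRIF-KO-labelled and the double-KO cells against 6.50 in wild-type and 6.59 in MyD88-KO cells, and Xist, transcribed from the inactive X chromosome, read 6.52 and 6.40 against 10.2 and 10.3. The sexes of the animals thus differed between the groups by these genes, although the labels call the mice gender matched.

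**Figure D1:**
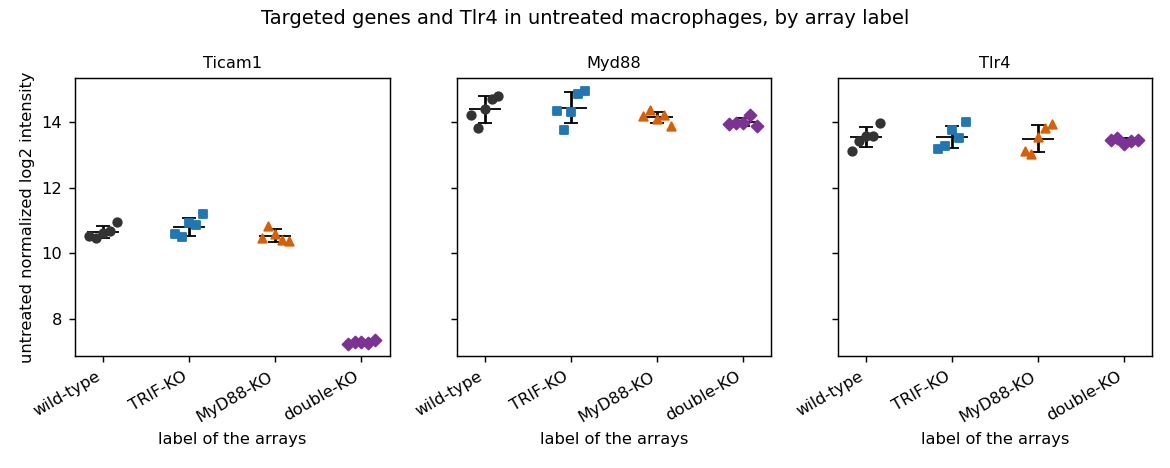
Normalized log2 intensity of Ticam1, Myd88 and Tlr4 in untreated macrophages (vertical axis) by the label of the arrays (horizontal axis), where each point is 1 array and the bars are the mean and SD of 5 arrays, with the MyD88-KO array of 2 h measured in the other dye. Ticam1 averages 10.6 in wild-type, 10.8 in TRIF-KO-labelled, 10.5 in MyD88-KO and 7.28 in double-KO cells, while Myd88 lies at 14.0 to 14.5 in each.

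LPS raised the classical inflammatory genes in every genotype that kept an adapter. Averaged over the 5 time points, Il6, which encodes a pyrogenic cytokine, rose 93.5-fold in wild-type cells (log2 6.55 ± 0.59 (SE), adjusted p = 1.2e-05), and Ptgs2, the inducible prostaglandin synthase, rose by 6.33 ± 0.52. Cxcl1, a neutrophil attractant, rose 112-fold in the TRIF-KO-labelled cells (6.81 ± 0.51) and by 5.93 ± 0.51 in wild-type and 3.17 ± 0.51 in MyD88-KO cells. Il1b rose by 5.17 ± 0.38, 5.14 ± 0.38 and 2.84 ± 0.38 in the same order of wild-type, TRIF-KO-labelled and MyD88-KO. Ifnb1, the interferon that drives antiviral genes, rose by 4.88 ± 0.86 in MyD88-KO cells (adjusted p = 0.0015), with 1.58 ± 0.86 in wild-type (adjusted p = 0.16) and 0.82 ± 0.86 in the TRIF-KO-labelled cells (adjusted p = 0.51). Untreated Ifnb1 in wild-type cells stood 2.44 at 8 h and 2.87 at 16 h above the mean of earlier times. In TRIF-KO-labelled cells it stood 2.96 and 3.43 above, and in MyD88-KO cells 0.91 and 0.32. The wild-type ratio was negative at those times, so its mean does not show the early rise. Cxcl10, which interferon induces, rose by 5.16 ± 0.66 in MyD88-KO and 2.81 ± 0.66 in wild-type cells and stood at 1.74 ± 0.66 in the TRIF-KO-labelled cells (adjusted p = 0.063). In limma's moderated test of 21961 genes, 7988 responded in wild-type (3667 higher, 4321 lower), 6381 in the TRIF-KO-labelled (2825 higher, 3556 lower) and 7791 in MyD88-KO cells (3681 higher, 4110 lower). Of 26 immediate early and NF-kB feedback genes, 24, 22 and 19 rose in these 3 groups, and of 23 inflammatory cytokines 21, 19 and 15 rose. These means hold a gene-specific dye effect because LPS was in Cy5 on 19 of 20 arrays. With a dye term, which rests on the single swapped array, 457, 323 and 844 genes passed, and with slide as a fixed block 0 (limma, 2373 at an unadjusted p under 0.05), 1957 and 1341 did.

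Without both adapters the inflammatory response was nearly flat. Tnf, the leading early cytokine, stood at 0.07 ± 0.21, Cxcl10 at 0.00 ± 0.66 and Nfkbia, the NF-kB inhibitor that NF-kB itself induces, at -0.22 ± 0.18 in double-KO cells. No member of the NF-kB feedback, cytokine, chemokine or interferon lists passed the threshold there, with median log2 ratios of -0.02 for the first, -0.03 for the second and -0.14 for the last. The spread in this test is shared by the 4 genotypes and holds the time courses of the responding cells, so small changes could be missed. The interferon median stood at -0.02, -0.09, -0.15, -0.04 and -0.30 at 1, 2, 4, 8 and 16 h. In all, 72 genes read higher and 1, Snx12, lower (-0.35 ± 0.07, adjusted p = 0.047). LPS was in Cy5 on every double-KO array. Their ratios correlated across genes at 0.44 to 0.63 with one another and at -0.24 to -0.10 with the swapped MyD88-KO 2 h array. With the other arrays, which had LPS in Cy5, they correlated at -0.08 to 0.38. These values go with a gene-specific dye effect, which cannot be told apart from a response to LPS here. The number of genes that passed depends on the processing. Scaling of log ratios gave 2416 (1701 higher, 715 lower), no background correction 325 and leaving out the MyD88-KO 2 h array 361. Scaling gives all arrays the same median absolute ratio. The SD of the ratios was, however, 0.13 to 0.20 on double-KO and 0.22 to 0.95 on other arrays. Scaling thus does not keep the difference between genotypes in the size of the response. The largest values in the main fit were those of Dennd4a with 1.07 ± 0.16, Sema4c with 1.04 ± 0.16 and Sp110 with 1.02 ± 0.16. The other probes of Dennd4a read -0.09 and -0.05 and that of Sp110 -0.04. With a dye term or with slide as a fixed block 0 genes passed in limma's test, with 534 and 832 at an unadjusted p under 0.05, and leaving out any 1 double-KO array left 0 or 1. Il6, Il1a, Il12b, Cxcl3, Cxcl5, Csf3 and Npy were not well above background in either channel of the double-KO arrays, so their ratios there compare values at the detection floor.

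**Figure D2:**
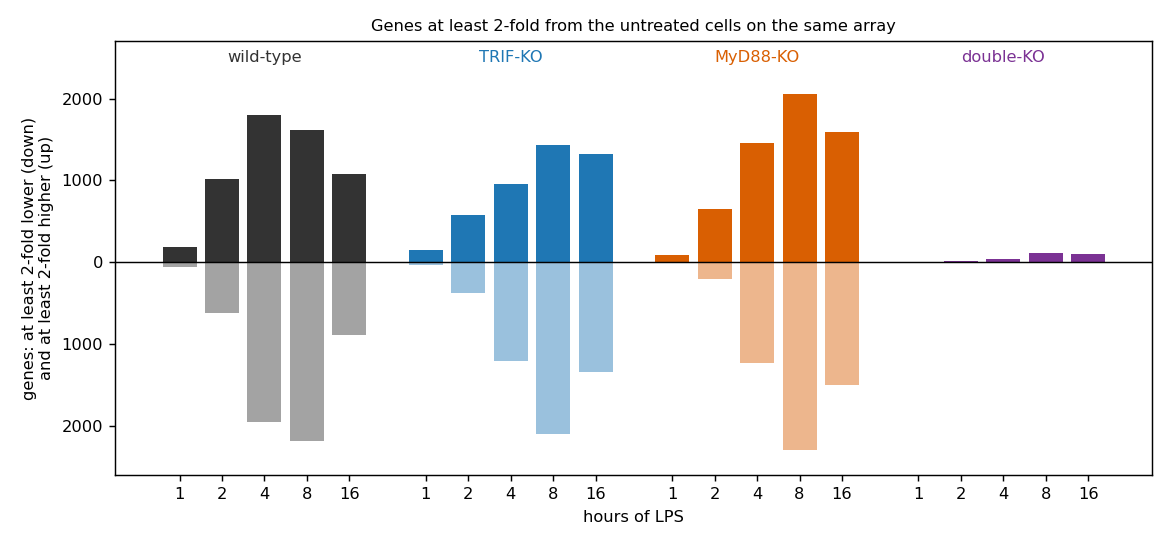
Number of genes at least 2-fold higher (upward bars) and at least 2-fold lower (downward bars) after LPS on each array, by genotype label and hours of LPS (horizontal axis), 1 array per bar. Wild-type arrays peak at 4 h with 1797 higher genes, MyD88-KO arrays at 8 h with 2054, and no double-KO array exceeds 109.

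**Figure D3:**
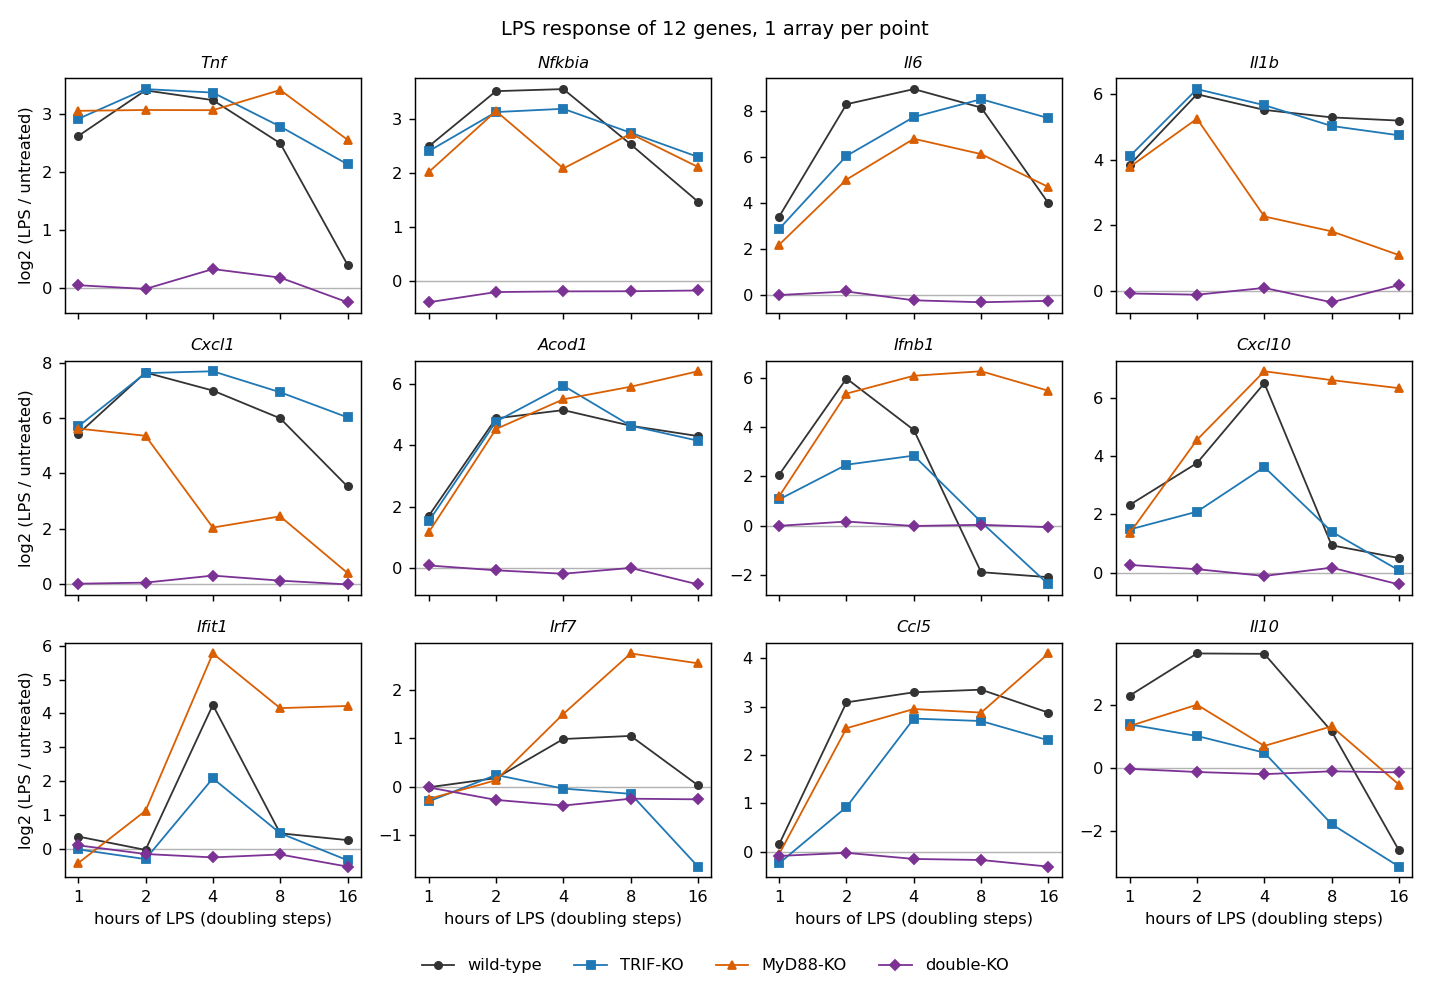
Log2 ratio of LPS-treated to untreated cells (vertical axis) against hours of LPS in doubling steps (horizontal axis) for 12 genes, with 1 array per point and 1 line per genotype label. Cxcl1 falls from 5.63 at 1 h to 0.39 at 16 h in MyD88-KO cells, Ifnb1 stays at 5.48 at 16 h in MyD88-KO cells and reaches -2.10 in wild-type cells, and Tnf in double-KO cells stays near 0. Untreated Ifnb1 in wild-type cells stood 2.87 higher at 16 h than the mean of 1, 2 and 4 h.

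The comparison of wild-type with double-KO asks what both adapters together contribute. The response of Cxcl1 was 57.2-fold larger in wild-type (log2 5.84 ± 0.72, n = 5 and 5) and that of Cxcl2, another chemokine of neutrophils, 4.91 ± 0.52 larger. Cxcl1 was well above background on 3 of 5 double-KO arrays in each channel and Cxcl2 on 4 untreated and 3 LPS-treated ones. Il1b differed by 5.23 ± 0.53, the collagenase Mmp13 by 4.33 ± 0.58, and the NF-kB antagonists Tnfaip3 and Nfkbia by 4.74 ± 0.45 and 2.93 ± 0.25 (adjusted p = 6.9e-05). Also larger in wild-type were Acod1, which makes itaconate (4.27 ± 0.61), Saa3 (3.15 ± 0.60), Nos2, the inducible nitric oxide synthase (2.75 ± 0.70), Ccl5 (2.70 ± 0.48) and Tnf (2.37 ± 0.29). Il6 (6.67 ± 0.83, adjusted p = 0.00071), Cxcl3 (5.32 ± 0.49), Il1a (5.03 ± 0.55) and Il12b (4.29 ± 0.80) passed as well, but they were not well above background in either channel of the double-KO arrays. Serpinb2, a plasminogen activator inhibitor (6.51 ± 0.85), and Ptgs2 (6.37 ± 0.74) were not in the LPS channel there. These 6 values set a response against values at or near the detection floor and have no order. Genes with a lower value in wild-type than in double-KO cells were led by Hpgd, which degrades prostaglandins (-2.73 ± 0.77, adjusted p = 0.035), Angptl4 (-2.37 ± 0.45), Rasgrp3 (-2.37 ± 0.63) and the transporter Slco2b1 (-2.22 ± 0.61). In all, 2639 of 21961 genes passed, 1303 higher and 1336 lower.

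By list, 21 of 26 NF-kB feedback genes were higher in wild-type than in double-KO cells and none lower (24 adjusted over the list alone, median 1.77, camera adjusted p = 1.2e-20), and 12 of 23 cytokines were (20 over the list alone, median 1.73, adjusted p = 1.5e-16). Of 21 chemokines 10 were higher (14 adjusted over the list alone, adjusted p = 3.6e-10), of 20 costimulatory and adhesion molecules 15 were and 1 was lower (18 and 1 over the list alone, 5.3e-12), and of 20 negative regulators of Toll-like receptor signalling 13 were and 1 was lower (17 and 2, 4.1e-12). Of 33 acute phase, complement and matrix proteins 16 were higher and 1 lower (19 and 3, 2.9e-08), and of 14 enzymes of nitric oxide, itaconate and prostaglandins 10 were higher (11 and 1, 2.3e-08). These 7 lists kept their call with an estimated correlation. Random regroupings of the arrays gave a median of 57 list calls over all results, against 89 in the real grouping. The camera p-values at the preset correlation, here and in later paragraphs, therefore overstate the evidence. Of 38 measured interferon-stimulated genes only 2 passed (0 adjusted over the list alone, median 0.70, adjusted p = 2.2e-06, and adjusted p = 0.51 with an estimated correlation). Ifnb1 stood at 1.57 ± 1.21 (adjusted p = 0.41), Cxcl10 at 2.80 ± 0.94 (0.063), Ifit1, an antiviral effector, at 1.26 ± 0.75 (0.28) and Il10 at 1.73 ± 0.71 (0.12). The Ifnb1 mean holds negative wild-type ratios at 8 and 16 h, where its untreated level was higher than before. Cell cycle genes were lower for 6 and higher for 1 of 27 (7 and 1 adjusted over the list alone, median -0.52, adjusted p = 0.002, and adjusted p = 0.5 with an estimated correlation). Stress and unfolded protein genes were higher for 8 of 20 (9 adjusted over the list alone, median 0.62, adjusted p = 2.2e-06, and adjusted p = 0.093 with an estimated correlation). With slide as a fixed block limma called 0 genes (865 at an unadjusted p under 0.05), the NF-kB list median turned to -0.65 and Ccl4 went from 3.55 ± 0.84 to -4.37; no slide held a time point of more than 1 genotype, so nothing could be matched within a slide. As a random block slide left 140 genes, no block of time points 256, these 2 groups alone 8, and the 4 h time point left out 167.

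**Figure D4:**
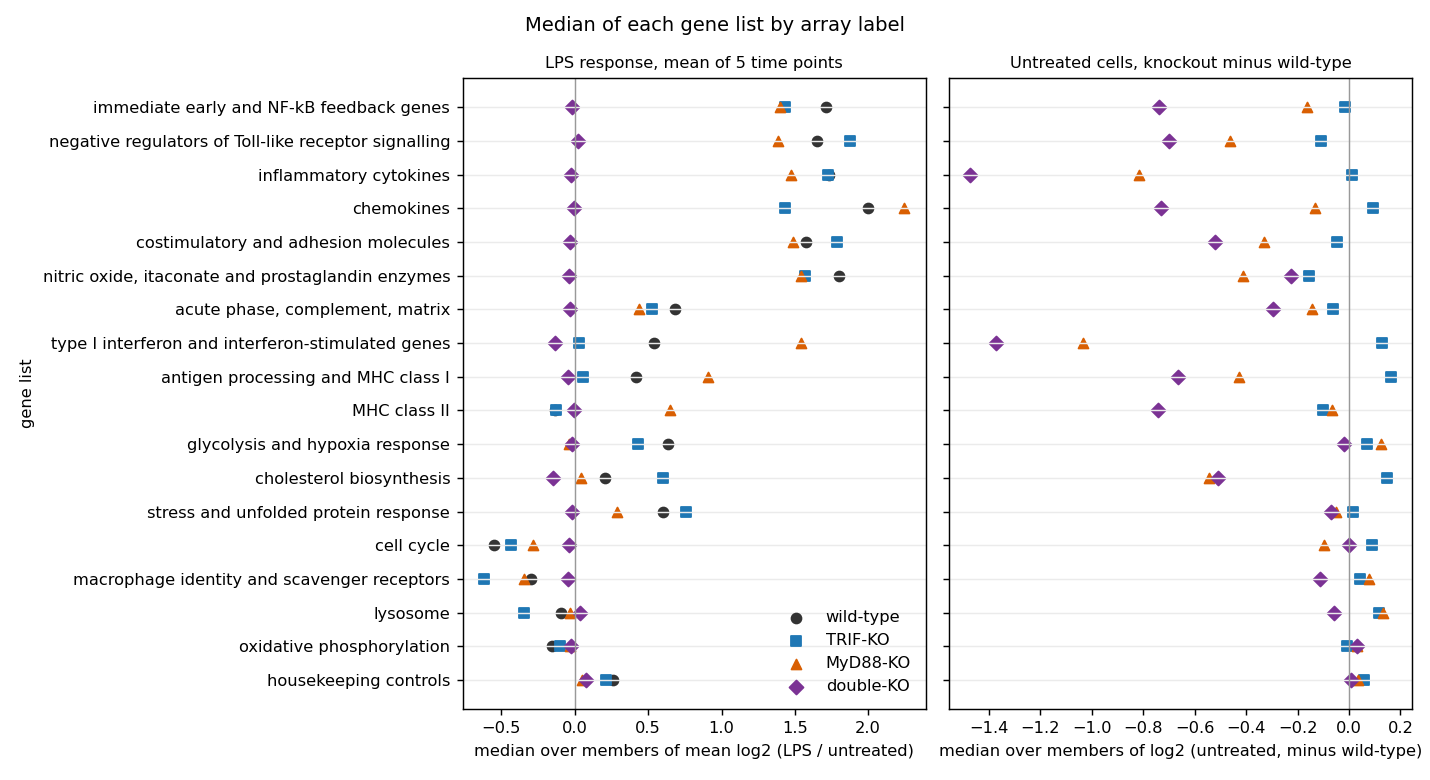
Median over the measured members of 18 gene lists (vertical axis) of the mean log2 LPS response per label (left, horizontal axis) and of the log2 difference of untreated knockout and wild-type cells (right, horizontal axis), with 1 symbol per label. The interferon list stands at 0.54 in wild-type, 0.03 in TRIF-KO-labelled and 1.54 in MyD88-KO cells after LPS, and at -1.03 in MyD88-KO and -1.37 in double-KO cells before it.

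The TRIF-KO-labelled cells were compared with double-KO cells to show what MyD88 contributes, as far as the label holds, since Ticam1 was at the wild-type level there. Their response was larger for Cxcl1 (105-fold, log2 6.72 ± 0.72, n = 5 and 5, adjusted p = 0.00029) and Cxcl2 (5.53 ± 0.52), again with only 3 or 4 of 5 double-KO arrays well above background. Il1b differed by 5.20 ± 0.53, Acod1 by 4.35 ± 0.61, Nfkbia by 2.98 ± 0.25 and Tnf by 2.86 ± 0.29. With double-KO values at or near the detection floor, and so without order, Il6 (6.69 ± 0.83), Ptgs2 (6.19 ± 0.74), Serpinb2 (5.71 ± 0.85), Cxcl3 (5.71 ± 0.49), Il1a (4.80 ± 0.55) and Il12b, a subunit of interleukins 12 and 23 (4.68 ± 0.80), passed too. The cystine transporter Slc7a11 differed by 4.52 ± 0.71 (adjusted p = 0.0046). Lower values than in double-KO cells were led by the chemokine receptor Ccr2 (-2.44 ± 0.68), Angptl4 (-2.43 ± 0.45) and Rgs2 (-2.07 ± 0.41). Interferon genes did not pass, with Ifnb1 at 0.81 ± 1.21 (adjusted p = 0.74), Cxcl10 at 1.73 ± 0.94 (0.28) and Ifit1 at 0.58 ± 0.75 (0.7). Altogether 1457 genes differed, 782 higher and 675 lower.

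Of the NF-kB feedback list 16 of 26 were higher (20 adjusted over the list alone, median 1.37, camera adjusted p = 1.2e-19), of the cytokines 11 of 23 (16, median 1.75, 5.3e-17) and of the chemokines 10 of 21 (15 and 1 lower, median 1.49, 8.6e-14), and each kept its call with an estimated correlation. The interferon list held 0 of 38 (0 adjusted over the list alone, median 0.19, adjusted p = 0.1). Cholesterol biosynthesis enzymes were higher for 7 of 21 (15 and 1 lower adjusted over the list alone, median 0.83, adjusted p = 4.5e-09, and adjusted p = 0.17 with an estimated correlation). Slide as a fixed block left 0 genes (limma, 4.60% of genes at an unadjusted p under 0.05), as a random block 164, and turned Rgs2 to 1.38. The model that did not block time points, as paired by the labels, left 76, scan day as a block 872, these 2 groups alone 74, and leaving out the 8 h arrays 50.

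MyD88-KO cells were set against double-KO cells for what TRIF contributes on its own. Cxcl10 responded 35.6-fold more (log2 5.15 ± 0.94, n = 5 and 5, adjusted p = 0.011) and Ifnb1 29-fold more (4.86 ± 1.21, adjusted p = 0.03, well above background on 3 of 5 double-KO arrays). Large differences were also found for Acod1 (4.84 ± 0.61), the adhesion molecule Vcam1 (4.69 ± 0.86), the activation antigen Cd69 (4.62 ± 0.80) and the chemokine Ccl12 (4.54 ± 0.89), and for Il6 (5.08 ± 0.83) and Ptgs2 (4.61 ± 0.74), whose double-KO values were at or near the detection floor. Tnfaip3 differed by 4.05 ± 0.45, the phosphatase Dusp2 by 3.98 ± 0.39, Cxcl1 by 3.09 ± 0.72, Tnf by 2.97 ± 0.29 and Il1b by 2.90 ± 0.53. Ifit1 (3.17 ± 0.75) and the ubiquitin-like Isg15 (2.61 ± 0.50) passed with the same sign at 4 of 5 time points, while Irf7 (1.57 ± 0.48, adjusted p = 0.053) and Il12b (2.64 ± 0.80, adjusted p = 0.051, also at the floor in double-KO cells) missed the threshold. Lower values were led by Angptl4 (-2.67 ± 0.45), Hpgd (-2.65 ± 0.77), Gpr34 (-2.52 ± 0.68) and thrombomodulin, Thbd (-2.50 ± 0.41). The total was 2210 genes, 1256 higher and 954 lower. With scaling of log ratios, which makes the spreads of the arrays alike, it was 2800, 1289 higher and 1511 lower, so the balance depends on the scaling.

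Of 38 interferon-stimulated genes 29 were higher in MyD88-KO than in double-KO cells (38 adjusted over the list alone, median 1.69, camera adjusted p = 6.7e-21, and adjusted p = 0.21 with an estimated correlation). Antigen processing and MHC class I genes were higher for 10 of 15 (13 adjusted over the list alone, median 0.98, adjusted p = 3.9e-08, and adjusted p = 0.21 with an estimated correlation). NF-kB feedback genes were higher for 16 of 26 (17 adjusted over the list alone, median 1.40, adjusted p = 1.3e-15, and adjusted p = 0.079 with an estimated correlation), cytokines for 11 of 23 (14, median 1.46, adjusted p = 6.2e-10, and adjusted p = 0.085 with an estimated correlation) and chemokines for 13 of 21 (15, median 2.13, adjusted p = 8e-10, and adjusted p = 0.079 with an estimated correlation). Slide as a fixed block left 0 genes (limma, 1641 at an unadjusted p under 0.05) with the interferon median at 1.86, as a random block 210, scan day as a block left 5527 with that median at 2.63, and without the block that pairs time points 60 genes passed. The count was 4 with these 2 groups alone, 89 without the TRIF-KO-labelled arrays, 29 without the 8 h time point and 5237 without the MyD88-KO arrays of 1 and 2 h, which were on another slide and scan day than the later ones.

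The genotypes with an adapter were then compared with each other, and no single gene passed. Between wild-type and the TRIF-KO-labelled cells, 0 of 21961 genes passed in limma's test (1648 at an unadjusted p under 0.05). The response of Il10, an anti-inflammatory cytokine, stood 2.02 ± 0.71 higher in wild-type with the same sign at 5 of 5 time points (adjusted p = 0.64) and that of Ccl5 0.86 ± 0.48 higher at 5 of 5 (0.7). Ifnb1 differed by 0.76 ± 1.21, Cxcl10 by 1.07 ± 0.94, Ifit1 by 0.68 ± 0.75, Irf7 by 0.82 ± 0.48 and Il6 by -0.01 ± 0.83. The interferon list was shifted to wild-type with a median of 0.63 (0 of 38 adjusted over the list alone, camera adjusted p = 1.9e-06, and adjusted p = 0.65 with an estimated correlation). At single time points Cxcl10 reached 6.51 in wild-type and 3.63 in the TRIF-KO-labelled cells at 4 h, and Ifnb1 5.97 and 2.47 at 2 h, without a replicate. All arrays of this pair were scanned on the same day, and with slide as a fixed block the interferon median turned to -0.31 and 1 gene passed. The direction also rests on a TRIF-KO label that the Ticam1 level does not bear out.

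Between wild-type and MyD88-KO cells 0 genes passed in limma's test (3186 at an unadjusted p under 0.05), with larger wild-type values for Il1a (3.00 ± 0.55, adjusted p = 0.14), Cxcl1 (2.75 ± 0.72, 0.17) and Il1b (2.33 ± 0.53, 0.14). Untreated Il1a was not well above background on any MyD88-KO array with untreated RNA in Cy3, so its difference rests on a value at the detection floor. Lower wild-type values were seen for Ifnb1 (-3.29 ± 1.21, adjusted p = 0.27), Cxcl10 (-2.35 ± 0.94, 0.29) and Ifit1 (-1.91 ± 0.75, 0.29). Part of the Ifnb1 difference lies in the untreated channel. There Ifnb1 stood above the mean of earlier times by 2.44 and 2.87 at 8 and 16 h in wild-type cells. In MyD88-KO cells it stood above by 0.91 and 0.32. The interferon list had a median of -0.95 (0 of 38 adjusted over the list alone, camera adjusted p = 2.9e-13, and adjusted p = 0.45 with an estimated correlation). Cytokines had a median of 0.65 (4 higher adjusted over the list alone, adjusted p = 0.00026, and adjusted p = 0.45 with an estimated correlation). Glycolysis and hypoxia genes had 0.67 (adjusted p = 4.5e-07, and adjusted p = 0.45 with an estimated correlation). Scan day as a block turned the interferon median to 0.25, and slide as a fixed block turned that of the cytokines to -6.0e-05, with 0 genes in limma's test under either (769 and 1801 at an unadjusted p under 0.05). Without the MyD88-KO 1 h array 410 genes passed, and without its 1 and 2 h arrays, a choice made after seeing the data, 2266 did (839 higher in wild-type, 1427 lower).

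Between the TRIF-KO-labelled and the MyD88-KO cells 0 genes passed in limma's test as well (4093 at an unadjusted p under 0.05). Inflammatory genes went both ways. Cxcl1 (3.63 ± 0.72), Il1a (2.78 ± 0.55) and Il1b (2.30 ± 0.53) had larger values in the TRIF-KO-labelled cells, and Ifnb1 (-4.05 ± 1.21), Cxcl10 (-3.42 ± 0.94), Ifit1 (-2.59 ± 0.75) and Irf7 (-1.71 ± 0.48) larger values in MyD88-KO cells, each with an adjusted p of 0.12. Untreated Il1a was not well above background on any MyD88-KO array with untreated RNA in Cy3, so its difference rests on a value at the detection floor. Untreated Ifnb1 stood above the mean of earlier times by 2.96 and 3.43 at 8 and 16 h in TRIF-KO-labelled cells. In MyD88-KO cells it stood above by 0.91 and 0.32. Tnf (-0.11 ± 0.29, adjusted p = 0.89) and Acod1 (-0.50 ± 0.61, 0.71) were lower in the TRIF-KO-labelled cells, and higher there with scaling of log ratios (0.03 and 0.17). The NF-kB list had a median of -0.05 (0 of 26 adjusted over the list alone, camera adjusted p = 0.85) and the chemokines -0.16 (7 higher and 4 lower over the list alone, 0.59), both with an upward mean and test and both above 0 with scaling (0.08 and 0.06). Cytokines had 0.32 (3 higher over the list alone, adjusted p = 0.027, and adjusted p = 0.66 with an estimated correlation), which turned to -0.21 with only probes well above background on all arrays. Adjusted over the list alone, 38 of 38 interferon-stimulated genes were lower in the TRIF-KO-labelled cells (median -1.63, camera adjusted p = 3.4e-23, and adjusted p = 0.57 with an estimated correlation), as were 11 of 15 MHC class I genes (median -0.92, adjusted p = 4.9e-08, and adjusted p = 0.57 with an estimated correlation). Cholesterol enzymes were higher for 10 of 21 adjusted over the list alone (median 0.75, adjusted p = 1.2e-07, and adjusted p = 0.57 with an estimated correlation). With scan day as a block the interferon median was -0.29. Without the MyD88-KO 1 h array 1336 genes passed, and without its 1 and 2 h arrays, chosen after seeing the data, 3108 did (1126 higher, 1982 lower).

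The response beyond additivity asks whether the response of wild-type cells equals the sum, on the log2 scale, of what each single knockout kept over the double-KO. That sum rests on a TRIF-KO label that the Ticam1 level does not bear out. Of the 29 genes that passed 22 were below the sum and 7 above. With scaling of log ratios between arrays, which makes their spreads alike, 198 passed, 100 below and 98 above, so the balance depends on the scaling. Relative to the sum Acod1 stood at -4.92 ± 0.86 (adjusted p = 0.043), Cxcl2 at -4.15 ± 0.74, the lectin receptor Clec4e at -3.97 ± 0.59, Gpr84 at -3.64 ± 0.57, Tnfsf9 at -3.62 ± 0.64 and Dusp2 at -3.61 ± 0.55. Tnf stood at -3.46 ± 0.41 (adjusted p = 0.0048), the monocyte attractant Ccl2 at -2.96 ± 0.46 and Nfkbia at -2.68 ± 0.36. Above the sum were Frat2 (2.46 ± 0.42), Vamp1 (0.87 ± 0.16) and the lysosomal Ppt1 (0.75 ± 0.11). Without the block that pairs time points 1 gene passed and with slide as a fixed block 3, while scan day as a block gave 1545. Leaving out the 8 h arrays gave 0 in limma's test (1254 at an unadjusted p under 0.05) and leaving out the double-KO 1 h array 653.

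Time trends were given per doubling of time. Relative to double-KO cells, the response of wild-type cells climbed for Slpi, a protease inhibitor (1.31 ± 0.17, adjusted p = 0.0044), Acsl1 (1.30 ± 0.15), Cd38 (1.30 ± 0.16), and the acute phase genes Saa2 (1.23 ± 0.20, not well above background in double-KO cells) and Hp (1.20 ± 0.16). It declined for Hpgd (-1.52 ± 0.31, adjusted p = 0.044), Ccr2 (-1.21 ± 0.21) and Cd5l (-1.08 ± 0.22). Of 21959 genes 118 passed, 60 up and 58 down, and 5 did without the double-KO 1 h array, 317 without the 16 h time point and 17 with slide as a fixed block. Between the TRIF-KO-labelled and MyD88-KO cells 852 trends differed, 305 up and 547 down. Cxcl5, a neutrophil attractant (1.53 ± 0.18, adjusted p = 0.0029, well above background after LPS on 2 of 5 MyD88-KO arrays), Ahr (1.09 ± 0.21) and Slc16a6 (1.08 ± 0.20) gained relative to MyD88-KO cells. Among the genes that lost ground were Ifit1bl1 (-2.34 ± 0.33), Fgl2 (-2.33 ± 0.41), Ccl8 (-2.04 ± 0.42), Iigp1 (-1.82 ± 0.45) and Irf7 (-1.13 ± 0.21). The interferon list, tested on trends only after the data were seen, held 5 lower members of 38 (27 adjusted over the list alone, median -0.85, camera adjusted p = 2e-14, and adjusted p = 0.36 with an estimated correlation). Slide as a fixed block left 0 of these genes in limma's test (1474 at an unadjusted p under 0.05) and turned Slc16a6 to -0.08, scan day as a block left 41, and without the 2 h time point 0 passed (2710 unadjusted).

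Untreated cells were compared to ask how the genotypes differed before LPS, in normalized log2 intensity of the Cy3 channel. The TRIF-KO-labelled cells differed from wild-type cells in 96 genes (47 higher, 49 lower). Eif2s3y was at least 177-fold and the Y-linked helicase Ddx3y at least 25.2-fold higher, and Xist at least 9.75-fold lower, where the dimmer group was not well above background. Lrmda was higher by 3.00 ± 0.11 (SE, n = 5 and 5), and Ankrd29 (67.2-fold, log2 -6.07 ± 0.14, adjusted p = 8.3e-13), Camk2b (-2.53 ± 0.10) and Gdf3 (-2.08 ± 0.09) were lower. Ticam1 differed by 0.16 ± 0.10 (adjusted p = 0.49). None of the 28 lists passed in camera, the interferon list standing at a median of 0.13 (camera adjusted p = 0.084). With slide as a fixed block 31 genes passed, without the block that pairs time points 32, with scan day as a block 298, and without the MyD88-KO 1 h array 297.

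MyD88-KO cells differed from wild-type cells before LPS in 2201 genes, 1397 higher and 804 lower. The scavenger receptor Marco (-4.13 ± 0.27, n = 4 and 5), the formyl peptide receptors Fpr1 (-4.11 ± 0.46) and Fpr2 (-3.68 ± 0.25), Cxcl1 (-3.40 ± 0.37, adjusted p = 9.4e-05), Camk2b (-4.13 ± 0.11) and Ankrd29 (-5.84 ± 0.16) were lower. Gdf3 (1.94 ± 0.10), Itga9 (1.90 ± 0.12) and the granule genes Ltf (1.90 ± 0.10) and Camp (1.84 ± 0.11) were higher. Interferon-stimulated genes were lower for 31 of 38 (36 adjusted over the list alone, median -1.03, camera adjusted p = 2.3e-27, and adjusted p = 0.059 with an estimated correlation), cytokines for 9 of 23 (14, median -0.82, adjusted p = 1.4e-07, and adjusted p = 0.12 with an estimated correlation) and cholesterol enzymes for 7 of 21 (16, median -0.54, adjusted p = 2.2e-09, and adjusted p = 0.19 with an estimated correlation). Markers of neutrophils and granulocyte precursors were higher for 8 of 12 (8 and 1 lower adjusted over the list alone, median 0.80, adjusted p = 2.1e-08), which held with an estimated correlation. Slide as a fixed block left 678 genes, no block for the paired time points 250, scan day as a block 266, leaving out the 8 h time point 389, and leaving out the MyD88-KO 1 h array gave 3664.

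Double-KO cells differed most from wild-type cells before LPS, in 5728 genes (3396 higher, 2332 lower). Inflammatory genes were low, with Saa3 at -5.62 ± 0.44 (n = 5 and 5, adjusted p = 5e-07), Acod1 at -4.87 ± 0.27, Socs3, a feedback inhibitor of cytokine signalling, at -4.79 ± 0.47, Tnf at -4.60 ± 0.43 (24.3-fold lower) and Ccl2 at -3.91 ± 0.42. Aoah, the enzyme that deacylates LPS, stood at -5.35 ± 0.16 and Ankrd29 at -5.55 ± 0.14, and Ticam1 was 10.3-fold lower (-3.36 ± 0.10, adjusted p = 5.5e-12). Npy was at least 31.4-fold lower. Eif2s3y was at least 176-fold higher, the protease gene Ctse 49.9-fold (5.64 ± 0.15) and Treml1 3.15 ± 0.17 higher. Lower were 36 of 38 interferon-stimulated genes (36 adjusted over the list alone, median -1.37, camera adjusted p = 1.4e-29), 14 of 26 NF-kB feedback genes with 1 higher (14 and 1, median -0.74, 6.2e-08) and 9 of 21 chemokines (10 lower and 1 higher, median -0.73, 1.3e-05), which kept their calls with an estimated correlation. The cytokines held 15 lower of 23 (15, median -1.47, 3e-08, and adjusted p = 0.056 with an estimated correlation). Slide as a fixed block left 1598 genes with the interferon median at -2.37, scan day as a block 1853 with it at -1.26, and the model that did not block the paired time points 2206. Leaving out the 8 h arrays gave 3061.

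Over time in serum-free medium, untreated cells of the 4 genotypes changed in 6872 genes, 3377 rising and 3495 falling. Per doubling of time Id3, an inhibitor of transcription factors, fell by 1.42 ± 0.09 (SE, 19 arrays, adjusted p = 1.2e-08), Cd34 by 1.41 ± 0.13, and the mitosis genes Birc5, Ccnb2 and Kif20a by 1.27 ± 0.13, 1.23 ± 0.17 and 1.17 ± 0.13. The glycine transporter Slc6a9 (1.04 ± 0.14), Dcstamp, needed for cell fusion (1.04 ± 0.17), Ccnd1 (0.94 ± 0.13) and complement factor B, Cfb (0.93 ± 0.11), rose. Without the 16 h arrays 4045 genes passed, and with slide as a fixed block 3872. Without both the 8 and the 16 h arrays, chosen after seeing the data, 2292 passed and Ccnd1 stood at -0.10.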

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

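The tests on Ticam1, on the low untreated levels and on the late rise of interferon genes were chosen only after those results were seen, whereas the counts over other splits of the samples were planned.

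The first 10 results were single arrays far from the other 4 of their genotype, by the ratio of the gap to the nearest array over the range, which exceeds 0.71 for a set of 5 about 1 time in 20 by chance. Of 144 such sets 10 exceeded it, and chance alone flags 5%. Since the 5 arrays are 5 time points, a time course that moves at 1 time only also gives such a gap. Ifit1 was highest in wild-type at 4 h (ratio 0.885), at 4.25 against 0.46 for the next array. Acod1 was lowest in wild-type at 1 h (0.755), at 1.70 against 4.30. In the TRIF-KO-labelled cells at 16 h the MHC class II median was lowest (0.731), at -1.50 against -0.06, and Irf7 was lowest (0.711), at -1.65 against -0.30. The housekeeping median was lowest there at 2 h (0.836), at -0.12 against 0.07. In MyD88-KO cells Ifnb1 was lowest at 1 h (0.821), at 1.19 against 5.36, and the cholesterol list at 16 h (0.741), at -1.13 against -0.02. The cholesterol list was also lowest at 16 h in double-KO cells (0.857), at -0.78 against -0.08. There the NF-kB feedback median at 4 h (0.741) stood at -0.10 against -0.03 and Nfkbia at 1 h (0.868) at -0.38 against -0.20.

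The other results here are differences between genotypes in the response to LPS that a test of the difference itself found: 2639 genes between wild-type and double-KO, 1457 between the TRIF-KO-labelled cells and double-KO, 2210 between MyD88-KO and double-KO, 29 beyond additivity, 118 trends between wild-type and double-KO and 852 trends between the TRIF-KO-labelled and MyD88-KO cells. Each was set beside 100 splits of the same arrays into groups of the same size, drawn from 126 where 2 groups were compared, the real split included. For wild-type against double-KO, 2 splits gave as many genes and the highest other gave 4106, above the real 2639. That split mixed the genotypes and left some time points together on 1 side, and what its count reflects was not tested. Chance is excluded at 0.05 only against splits that ignore the time points. Of the 12 splits that parted every time point, too few for a share under 0.05, the highest other gave 769. For the TRIF-KO-labelled cells against double-KO 2 splits did, with 2008 as the highest other, above the real 1457. The same limit holds there, with 0 as the highest other of the 12 splits that parted every time point. For MyD88-KO against double-KO 4 of the 100 did, with 4650 as the highest other, again from a split that left some time points together on 1 side. Of the 12 splits there that parted every time point, too few for a share under 0.05, another gave 2388, above the real 2210, so that chance is excluded only against splits that ignore the time points. Beyond additivity only the real grouping, 1 of 100, gave as many as 29, the highest other giving 0. The others were random regroupings, and none that keeps the time points apart was counted. The comparison therefore bears only on regroupings that ignore the time points, and chance is not excluded against those that respect them. Of the trends, 3 splits matched the 118 of wild-type against double-KO (highest other 331, above the real count). This excludes chance only against splits that ignore the time points, and the highest other of the 12 that parted every time point gave 64. For the TRIF-KO-labelled against MyD88-KO cells 6 splits matched the 852 (highest other 1724), which does not exclude chance. None of the other splits among the 12 that parted every time point gave more than 660 there, but 12 are too few for a share under 0.05. The 3 comparisons with 0 genes in limma (unadjusted counts in the report) are matched by all 100 splits whatever the samples, since no split gives fewer, which says nothing on chance. The highest others were 53 for wild-type against the TRIF-KO-labelled cells, 912 for wild-type against MyD88-KO and 1281 for the TRIF-KO-labelled against MyD88-KO cells. Those splits left some time points together on 1 side: among the 12 that parted every pair of time points, as the real one does, the highest were 0, 1 and 1. Untreated levels gave 1 split as large for the TRIF-KO-labelled cells (real 96, highest other 5), 2 for MyD88-KO (2201 and 2683, above the real count) and 1 for double-KO (5728 and 1718). Chance can be excluded for each against splits that ignore the time points. Other splits parting the time points gave at most 0 for the TRIF-KO-labelled and 1 for double-KO cells. These were 12 splits for each, too few for a share under 0.05. For MyD88-KO the 38 splits counted had distinct time points only in the group of 4 arrays. Their group of 5 could hold both arrays of a time point. Their highest other of 980 therefore does not tell what splits parting every time point give. For the 89 list shifts 8 regroupings gave as many, up to 99 with a median of 57, so chance cannot be excluded for their number.

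Ticam1 at the wild-type level on the arrays labelled TRIF-KO was the first pattern weighed. RNA of the wild-type cultures on those arrays is argued against by Ankrd29, which stood at -6.07 relative to wild-type, and by the sex-linked genes, which also set them apart. What stays open is an allele that leaves the transcript in place while the TRIF-dependent response is lost: interferon genes then should respond less than in wild-type, and their list was shifted that way with an adjusted p of 0.649 under an estimated correlation, which decides nothing. Whether the animals carried such an allele was not tested, and the probe position within the gene was not annotated here.

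The low untreated cytokine and interferon genes of the arrays without MyD88 were the second pattern. Over the 51 members lower in double-KO cells the median was -1.50 there (quartiles -2.31 and -1.21) and -1.08 in MyD88-KO cells. Sex of the animals is argued against as the cause for double-KO cells, because the TRIF-KO-labelled cells share their sex-linked expression and had a median of 0.0625 (quartiles -0.12 and 0.20) over the same members. Scan day stays open for double-KO cells, all scanned on day 2. The MyD88-KO arrays of 1 and 2 h were scanned on day 1, the latter with untreated RNA in Cy5. At 1 h the untreated interferon median was 13.9 in MyD88-KO, 14.7 in wild-type and 15.1 in TRIF-KO-labelled cells. The cytokine medians were 8.12, 8.97 and 8.67. At 2 h they were 13.8, 14.7 and 14.9, and 8.17, 8.90 and 8.47. These values argue against scan day as the only source in MyD88-KO cells, though slides differed. The fit of untreated levels held only 1 array without MyD88 from day 1. With scan day in that fit the medians of the 51 members were -1.33 in double-KO and -0.91 in MyD88-KO cells. Of these members 24 passed in double-KO and 6, down from 38, in MyD88-KO cells. Loss of a tonic signal through MyD88 may contribute, but in double-KO cells it cannot be told apart from scan day.

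Interferon genes that were higher in untreated wild-type cells at 8 h than at 1 to 4 h were the third pattern. Slide and scan day are argued against, because the median rise was 1.1 (quartiles 0.89 and 1.33, 35 of 36 members up) between arrays of 1 slide and scan day. No early array stood more than 0.13 above their mean, and the list medians were 14.7, 14.7, 14.3 and 15.7 at 1, 2, 4 and 8 h. LPS in the untreated wells was checked on 184 other genes that LPS raised at least 4-fold at 1 to 4 h. Their median rose by 0.15 (quartiles -0.18 and 0.62), below the interferon rise. Tnf stood at -0.97 and Cxcl1 at -0.75, but Il10 at 1.43 and Ifnb1 at 2.44. Untreated medians of other lists differed in this. At 1, 2, 4 and 8 h the cytokines stood at 8.97, 8.90, 9.79 and 10.5. The nitric oxide, itaconate and prostaglandin enzymes stood at 10.2, 10.7, 11.5 and 12.8, and the NF-kB feedback genes at 12.6, 12.2, 12.8 and 12.9. LPS in the wells therefore stays open. A rise of interferon signalling with time in culture of wild-type cells may be biological, but LPS is not excluded. The hypothesis was found and tested on the same data. At 8 h it was 1.28 in the TRIF-KO-labelled cells, where the other genes rose by 0.44 and Tnf by 0.97 so that LPS stays open, and smaller in MyD88-KO (0.57) and double-KO cells (0.59), but 0 scan days held late arrays of both kinds, so genotype and scan day cannot be told apart there.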

How the results depend on the processing

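Scan day as a block and the fits without the MyD88-KO arrays of 1 and 2 h, the 8 and 16 h arrays, the TRIF-KO arrays or the double-KO arrays were chosen only after the data were seen. Of 10231 comparisons of 250 named values with an alternative, 9069 kept direction and side of the threshold, 903 lost and 121 gained a call, 120 changed sign without a call and 18 reversed. List trends were not run under alternatives. With 1 array or time point left out none of 6250 reversed and 490 lost a call. Counts are given in the order of the results named. With slide as a fixed block the mean responses of wild-type, TRIF-KO-labelled, MyD88-KO and double-KO cells had 0, 1957, 1341 and 0 genes, the responses of these against double-KO 0, 0 and 0, wild-type against TRIF-KO-labelled 1, additivity 3, the trends of wild-type minus double-KO and of TRIF-KO-labelled minus MyD88-KO 17 and 0, untreated TRIF-KO-labelled, MyD88-KO and double-KO cells 31, 678 and 1598, and the untreated trend 3872. In limma the counts of 0 had unadjusted p under 0.05 for 2373 (wild-type mean), 832 (double-KO mean), 865 (wild-type against double-KO), 4.60% of genes (TRIF-KO-labelled against double-KO), 1641 (MyD88-KO against double-KO) and 1474 genes (second trend). It reversed the medians of NF-kB feedback (-0.65), negative regulator (-0.58), stress (-0.30) and Tlr4 pathway genes (-0.38) and Ccl4 (-4.37), Cxcl1 (-0.95), Cxcl2 (-0.91), Il12b (-2.22, at the detection floor in double-KO cells) and Mmp13 (-1.80) in wild-type minus double-KO, interferon genes in wild-type minus TRIF-KO-labelled (-0.31), cytokines in wild-type minus MyD88-KO (-6.0e-05), Rgs2 (1.38) and the trend of Slc16a6 (-0.0764). Slide as a random block (correlation 0.200 for ratios, 0.407 for untreated levels) gave 4505 and 4763 for the wild-type and MyD88-KO means, 0 for double-KO (784 unadjusted in limma), 140, 164 and 210 against double-KO, 10 for additivity, 69 and 147 for trends, and 37, 625 and 2014 for untreated cells. Scan day gave 1 for the double-KO mean, 872 and 5527 for TRIF-KO-labelled and MyD88-KO against double-KO, 1545 for additivity, 41 for the second trend and 298, 266 and 1853 for untreated cells, and reversed the interferon median of wild-type minus MyD88-KO (0.25) and the glycolysis (-0.35) and cholesterol medians (-0.0965) of wild-type minus double-KO. No slide held the same time point of more than 1 genotype, and wild-type and TRIF-KO-labelled arrays fell on day 1 only and double-KO arrays on day 2 only, so these terms take up genotype too. Without the block of time points, which the labels pair, the counts were 5191, 3735 and 4942 for the means, 256, 76 and 60 against double-KO, 1 for additivity and 32, 250 and 2206 for untreated cells, and of the named lists only MHC class II in untreated double-KO cells lost its call, while leaving the block out changed no other count by over 1.5 times. Only the groups compared gave 8, 74 and 4 against double-KO and 432 for untreated TRIF-KO-labelled cells. A dye term gave 457, 323, 844 and 0 (534 unadjusted in limma) for the means, 2 for wild-type and 2 for TRIF-KO-labelled against MyD88-KO and 13 for additivity. Scaling of log ratios gave 3235, 3728 and 2416 (1701 higher and 715 lower) for the wild-type, MyD88-KO and double-KO means, 2503 for TRIF-KO-labelled against double-KO, 2800 (1289 and 1511) for MyD88-KO against double-KO, 198 (98 and 100) for additivity, and 211 and 143 (31 and 112) for trends, while array medians lay between -0.0494 and 0.0450 under every scaling. The scanner's processed intensities gave 1 and 1 for wild-type and TRIF-KO-labelled against MyD88-KO, 50 for additivity and 451 for the second trend, and the value table of the series gave 112 for the double-KO mean, 1 and 1, 52, and 77 and 496 for trends. Without background correction the double-KO mean had 325 genes. Only probes well above background on all arrays reversed the cytokine median of TRIF-KO-labelled minus MyD88-KO (-0.21). No filter on dim probes gave 44 for it, 1408 for MyD88-KO against double-KO and 18 for additivity, and the mean of probes 17 for it. Without the MyD88-KO arrays of 1 and 2 h the counts were 388 for the double-KO mean, 5237 for MyD88-KO against double-KO, 2266 and 3108 for wild-type and TRIF-KO-labelled against MyD88-KO, 1351 for additivity, 212 for the second trend and 297 and 3664 for untreated TRIF-KO-labelled and MyD88-KO cells. Without 8 and 16 h they were 1977, 418 and 0 (1238 unadjusted in limma) for the TRIF-KO-labelled, MyD88-KO and double-KO means, 622, 29 and 14 against double-KO, 3 for additivity, 146 and 2607 for untreated MyD88-KO and double-KO cells and 2292 for the untreated trend, where Ccnd1 reversed (-0.10). Without TRIF-KO arrays the double-KO mean had 0 (1220 unadjusted in limma), and wild-type and MyD88-KO against double-KO had 774 and 89. Of the 89 list calls 20 held with an estimated correlation. Leaving out each array or time point gave 3849 (no 4 h) to 8441 for the wild-type mean, 2815 (no 8 h) to 6687 for TRIF-KO-labelled, 2118 (no 8 h) to 8351 for MyD88-KO and 0 (no double-KO 1 h, 1715 unadjusted in limma) to 361 (no MyD88-KO 2 h) for double-KO, then 167 (no 4 h) to 4112, 50 (no 8 h) to 3223 and 29 (no 8 h) to 4298 against double-KO, each highest without double-KO 1 h. It gave 0 to 1 (no TRIF-KO 1 h) for wild-type against TRIF-KO-labelled, 0 to 410 and 0 to 1336 (no MyD88-KO 1 h) against MyD88-KO, 0 (no 8 h, 1254 unadjusted in limma) to 653 (no double-KO 1 h) for additivity, 5 (no double-KO 1 h) to 317 (no 16 h) and 0 (no 2 h, 2710 unadjusted in limma) to 1123 (no wild-type 16 h) for trends, 35 (no 8 h) to 297 (no MyD88-KO 1 h), 389 (no 8 h) to 3664 (no MyD88-KO 1 h) and 3061 (no 8 h) to 6318 for untreated cells, 4045 (no 16 h) to 7010 for the untreated trend and 79 to 93 for lists. Beyond 1.5 times lay 4, 4, 4 and 19 of 25 such fits for the means, 9, 12 and 19 against double-KO, 22 for additivity, 13 and 7 for trends, 14, 10 and 2 for untreated cells, 1 for the untreated trend and 0 for lists. Against double-KO, wild-type gave 1192, 930 and 878 without its 2, 4 or 8 h array, 834 and 748 without double-KO 4 or 8 h and 860 and 180 without the 2 or 8 h time point. There TRIF-KO-labelled gave 409, 242 and 400 without its 4, 8 or 16 h array, 270, 237 and 752 without double-KO 4, 8 or 16 h and 2368, 529, 65 and 260 without 1, 2, 4 or 16 h. MyD88-KO gave 3843, 277, 245 and 265 without its 1, 4, 8 or 16 h array, 205, 204 and 943 without double-KO 4, 8 or 16 h and 3977, 1205, 40 and 209 without 1, 2, 4 or 16 h. Without MyD88-KO 1 h or the 1 h time point additivity had 230 and 366 genes and the second trend 560 and 311, and without the 1 h time point wild-type and TRIF-KO-labelled against MyD88-KO had 171 and 624. Fewer arrays widen the errors, and for the other changes the cause was not tested. Signal over background limits what double-KO ratios can show for genes dim in both channels.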

Other observations

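The tests on time trends of lists given here were chosen only after the data were seen, and single time points carry no replicate. In MyD88-KO cells at 1 h Cxcl1 stood at 5.63 and Il1b at 3.77, against 5.43 and 3.84 in wild-type cells, and at 4 h at 2.04 and 2.26 against 7.01 and 5.52. Lists differed in this: at 1 h, on 1 array per genotype, the NF-kB feedback list had a median of 1.23 against 1.36 in wild-type cells and the cytokine list 0.22 against 0.78, and 85 genes were at least 2-fold higher against 183. The interferon list had a median of 2.70 at 8 h and 2.66 at 16 h in MyD88-KO cells, and 0.63 and -0.29 in wild-type cells, after 2.65 and 1.85 at 4 h. Because the ratio is taken against untreated cells of the same time, part of this lies in the untreated channel, where the same list stood at 14.7 at 1 h and 16.1 at 16 h in wild-type cells and at 13.9 and 14.6 in MyD88-KO cells. Untreated Ifnb1 in wild-type cells stood 2.44 at 8 h and 2.87 at 16 h above the mean of the earlier times, and its ratio after LPS was -1.90 and -2.10 there. The MyD88-KO arrays of 1 and 2 h were on another slide and scan day than the later ones, and they carried the same label-separating levels, with Itga9 at 9.10 and 9.15 and Ankrd29 at 7.38 and 7.44.

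Between wild-type and double-KO responses, glycolysis and hypoxia genes were higher for 5 of 20 (5 adjusted over the list alone, median 0.71, camera adjusted p = 1.7e-05, and adjusted p = 0.26 with an estimated correlation, but a median of -0.35 with scan day as a block), cholesterol enzymes for 4 of 21 (4 and 1 lower, median 0.46, adjusted p = 0.0021, and adjusted p = 0.5 with an estimated correlation, but -0.10 with scan day as a block), and components of the Tlr4 pathway for 4 of 20 with 2 lower (5 and 2, median 0.28, adjusted p = 0.012, and adjusted p = 0.26 with an estimated correlation, but -0.38 with slide as a fixed block). No member of the MHC class I list passed (0 of 15, also adjusted over the list alone, median 0.43, adjusted p = 0.0016, and adjusted p = 0.5 with an estimated correlation) and none of MHC class II (0 of 8, median -0.08, adjusted p = 0.89). Macrophage identity genes were higher for 3 and lower for 3 of 24 (3 and 4 adjusted over the list alone, median -0.31, adjusted p = 0.76), lysosomal genes for 2 and 3 of 25 (2 and 3, median -0.24, adjusted p = 0.14), and oxidative phosphorylation genes lower for 3 of 22 (3, median -0.07, adjusted p = 0.18). Housekeeping genes were higher for 2 and lower for 2 of 14 (2 and 3, adjusted p = 0.75), with a median of -0.02 but a mean of 0.04 and an upward test. MHC class II was higher for 2 of 8 in MyD88-KO against double-KO cells (2 adjusted over the list alone, median 0.65, adjusted p = 0.0069, and adjusted p = 0.42 with an estimated correlation). Before LPS, 6 of its 8 genes were lower in double-KO than in wild-type cells (6 over the list alone, median -0.74, adjusted p = 0.0037, and adjusted p = 0.14 with an estimated correlation).

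Markers of other cell types did not pass in camera between wild-type and double-KO responses, whereas fry gave adjusted p = 0.0087 for lower B cell, 0.016 for higher fibroblast and stroma and 0.024 for higher mast cell and basophil markers. T cell markers had 0 of 6 called (median 0.04, camera adjusted p = 0.54), B cell markers 2 lower of 7 (-0.23, 0.087), fibroblast and stroma markers 2 higher of 8 (3 adjusted over the list alone, 0.08, 0.13), dendritic cell markers 1 higher of 8 (0.02, 0.6), NK cell markers 1 lower of 6 (-0.07, 0.75), erythroid markers 0 of 4 (2 higher and 1 lower adjusted over the list alone, -0.03 with an upward test, 0.75), mast cell and basophil markers 1 higher of 5 (0.17, 0.12) and osteoclast markers 1 higher of 8 (2 higher and 2 lower adjusted over the list alone, 0.17 with a mean of -0.05, 0.54). Neutrophil and granulocyte precursor markers had 0 of 12 (-0.09 with a mean of 0.01 and an upward test, 0.98). In untreated double-KO cells the same neutrophil list had 2 higher and 2 lower of 12 (2 and 2 adjusted over the list alone, median 0.07 with a mean of -0.08, adjusted p = 0.74), against 8 higher in untreated MyD88-KO cells. The difference between those genotypes was not tested. No other marker list passed in camera in untreated MyD88-KO or double-KO cells, but fry gave adjusted p = 0.0018 for higher osteoclast, 0.0034 for higher fibroblast, 0.0050 for higher mast cell, 0.023 for lower NK cell and 0.027 for lower erythroid markers in MyD88-KO cells. In double-KO cells it gave 0.0049 for higher osteoclast, 0.0070 for higher fibroblast, 0.010 for higher dendritic cell and 0.016 for lower mast cell markers. B cell markers were lower in the TRIF-KO-labelled than in the double-KO responses for 2 of 7 (3 adjusted over the list alone, median -0.20, camera adjusted p = 0.021, and adjusted p = 0.16 with an estimated correlation).

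Trends of the single-knockout responses were tested for the lists after the data were seen. MHC class I genes lost ground in the TRIF-KO-labelled relative to MyD88-KO cells for 7 of 15 (12 adjusted over the list alone, median -0.54, camera adjusted p = 1.6e-09, and adjusted p = 0.21 with an estimated correlation). In wild-type relative to double-KO cells glycolysis and hypoxia genes gained for 1 of 20 (7 gained and 1 lost adjusted over the list alone, median 0.48, adjusted p = 3e-07, and adjusted p = 0.091 with an estimated correlation).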
